A study of Mus musculus with 18 samples.

How the data were processed

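The values are log2(CPM + 1), with CPM for counts per 1000000 reads, as deposited by the authors in a single table of 19862 genes and 18 libraries. Undoing the log2 and scaling to 1000000 per library returned whole reads for 100% of values within a tolerance of 0.1, which gave the depths of 32.3 to 57.9 M reads. Per the submitters' processing notes, reads were aligned with STAR to mm10 and the values were made with edgeR, with no versions given. The read counter, its annotation and its strand setting are not given in the sources used here, so genes that overlap another gene, close paralogs and genes with the same values are uncertain. Of the gene symbols, 336 were missing, 27 had been turned into dates and 362 were renamed from RefSeq, whose table held 19808 of the gene identifiers. Coding lengths were available for 17400 genes.

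The comparisons, the test, the gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. That design assumed read counts and named a fallback for logged values, which was used: limma with a trend and robust variances on the deposited values, with 6 group means over the 18 libraries. Genes above 0 in at least 3 libraries were tested, 17515 in all, and called at a Benjamini-Hochberg adjusted p under 0.05. A log2 change is therefore a change of log2(CPM + 1), which is smaller than that of CPM for genes of low level. Replicate libraries correlated at 0.945 to 0.996, and their chi-square per degree of freedom was 12.8 to 254, far more than counting noise gives. The analysis ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

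A simulation added known changes to 100 genes for each fold. At log2 1 the test recovered 83% (Total), 81% (Light), 81% (Heavy), 48% (Heavy over Light), 43% (Heavy over Total) and 72% (Heavy against Light). At log2 0.59 it recovered 48%, 41%, 40%, 7%, 7% and 28%, so the interactions missed most. False calls were 30, 6, 11, 1, 4 and 6 among 17315 unchanged genes. Their share of calls exceeded the adjusted p limit except in Light and Heavy over Light. Real libraries spread unequally and deviate together, so these rates may not hold.

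Of 32 gene lists fixed in advance, 31 were tested, and the mitochondrially encoded list had 0 members in the table. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists within a comparison. The naming rule took, for each comparison, the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 5 CPM, without unnamed gene models, and within a fraction only genes whose groups did not overlap. To these it added Prmt1 and its family, a few translation factors and oncogenes, and list members with the lowest p. The text prints only some of the genes the rule gives, mostly those whose call held over more alternatives, a selection made after the values were seen.

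Alternatives fixed in advance were quantile normalization, other filters, limma without trend, the libraries of a comparison alone, a pseudocount of 0.1, a replicate block, and leaving out each library. Alternatives chosen after seeing the data were voom and median-of-ratios scaling on the recovered reads, a mean of at least 1 CPM, coding genes only, removal of the coding-length trend over 50 bins, leaving out all knockout libraries numbered 1, and the block with that trend removed. Pairing libraries by number was checked by correlating deviations from the group means. Heavy and Light pairs deviated together, at 0.368 to 0.471 in control and 0.263 to 0.641 in knockout cells. Light and Total did so in knockout cells (0.461 to 0.648) but not in every control pair (-0.681 to 0.383). Control Light 1 and 3 instead went with Total 3 and 1 (0.736 and 0.831), so a block may mispair Total controls. Raw reads were not analysed here.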

Results

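The libraries come from murine osteosarcoma cells that carry floxed Prmt1 alleles and a tamoxifen-inducible Cre recombinase. Prmt1 encodes the main asymmetric arginine methyltransferase of mammalian cells. Cells given ethanol served as controls, and cells given 4-hydroxytamoxifen are called knockout cells. Cytoplasmic lysate was kept as Total RNA or spread over a sucrose gradient, which separates messages by the ribosomes they carry, and pooled into Light (fewer than 3 ribosomes) and Heavy (more than 3 ribosomes) fractions. Each of the 6 groups has n = 3 libraries. SDs are per group, but each SE pools the spread of all 6. The values are shares of a library, in counts per 1000000 (CPM), so a message higher in Heavy made up more of the Heavy RNA, which is not a rate of translation. No cells without floxed alleles that were given 4-hydroxytamoxifen are among these libraries, so effects of the drug or of Cre are not separated from those of the deletion. Nothing states that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

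The deposited values correspond to 39.8, 35.7 and 44.2 M reads (M for 1000000) in the Heavy control libraries numbered 1 to 3 and 40.4, 37.9 and 32.3 M in the Heavy knockout libraries. The Light control libraries hold 57.9, 48.9 and 38.7 M reads and the Light knockout libraries 50.8, 35.9 and 50.7 M. The Total control libraries hold 37.6, 52.1 and 32.8 M and the Total knockout libraries 34.1, 41.6 and 40.9 M. The knockout library numbered 1 lay farthest from its group mean in every fraction, with a root mean square deviation of 0.349 (log2) in Heavy, 0.239 in Light and 0.196 in Total. These compare with 0.161 and 0.251, 0.156 and 0.163, and 0.112 and 0.130 for the other knockout libraries. Without the knockout libraries numbered 1, a choice made after seeing the data, 5367 genes were called in Total, 7374 in Light and 5353 in Heavy.

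Prmt1 itself (gene 15469, chromosome 7, 44976755 to 44986420 on the minus strand of mm10) was lower in knockout than in control cells in Total and Heavy RNA but not detectably so in Light RNA. Its level was 256, 277 and 285 CPM in the Total control libraries and 147, 176 and 173 CPM in the Total knockout libraries, a log2 change of -0.72 (SE 0.21, limma adjusted p = 0.0202). In Heavy RNA it was 412, 378 and 370.1 CPM in control libraries and 64.4, 121 and 145 CPM in knockout libraries (-1.88, SE 0.21, adjusted p = 7.87e-06). In Light RNA it was 255, 243 and 218 CPM against 166, 229 and 235 CPM (-0.20, SE 0.21, adjusted p = 0.506). The Total call was lost without Total control 2 (adjusted p = 0.0562), Total control 3 (0.0614) or Total knockout 1 (0.0809), within a range of 0.000168 to 0.0809 over its alternatives. Which exons were deleted is not given in the sources used here, and reads from remaining exons count toward the gene.

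**Figure D1:**
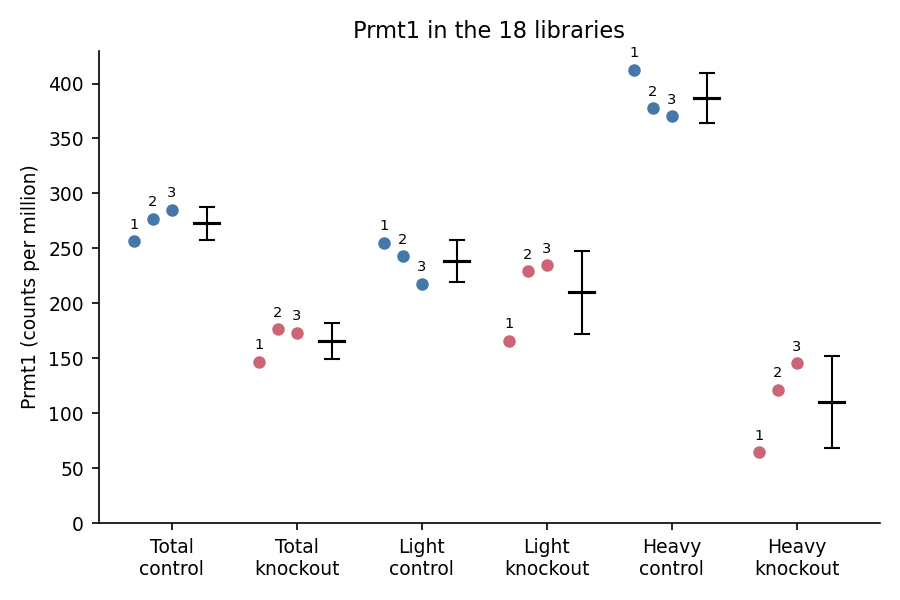
Prmt1 in CPM in each of the 18 libraries, grouped by fraction and genotype; points are libraries, labelled with their replicate number, and the bars beside them are means with SD. All 3 Heavy knockout libraries, at 64.4 to 145 CPM, lie under all 3 Heavy control libraries, at 370.1 to 412 CPM, while the Light groups overlap.

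The comparison of Total RNA asks which cytoplasmic messages changed in abundance after loss of Prmt1. Of the lists fixed in advance, 29 of 45 interferon-stimulated genes rose in knockout cells and none fell. Lower were 17 of 47 DNA replication, 10 of 43 mitosis, 14 of 32 DNA repair and 8 of 40 ribosome biogenesis genes, with 2 DNA repair genes higher, and none of these lists passed with an estimated correlation (adjusted p = 0.271 to 0.316). C3, the central complement component, rose from 0.484 ± 0.120 to 29.1 ± 13.7 CPM (log2 change 4.25, SE 0.39), and the GPI-anchored surface antigen Ly6a from 6.45 ± 0.428 to 111 ± 65.4 CPM. Also among the highest changes were the interferon-induced GTPase Gbp2 (3.71, SE 0.30), the surface glycoprotein Msln (3.64, SE 0.31), the Wnt antagonist Sfrp1 (3.39, SE 0.45) and the apoptosis factor Xaf1 (3.33, SE 0.24). The lowest included the hyaluronan synthase Has2, which fell from 42.0 ± 8.04 to 5.32 ± 1.98 CPM, Igfbp7, a secreted binder of insulin-like growth factors that overlaps Polr2b (-2.71, SE 0.10), the vasopressin receptor Avpr1a (-2.68, SE 0.12) and the neutrophil chemokine Cxcl5 (-2.60, SE 0.21). The proliferin genes fell too, Prl2c2 by most (-3.19, SE 0.40), but Prl2c3 and Prl2c4 have nearly the same values, so which member fell is uncertain. The histone genes Hist2h3c1 and Hist2h3c2 also have identical values (3.24, SE 0.17). Each of these genes had a limma adjusted p of 4.11e-05 or lower.

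In all, limma called 4628 of 17515 genes, 2820 higher and 1808 lower (60.9% higher), of which 576 and 250 changed at least 2-fold on the log2 scale. The share called higher was 48.9% of 4463 genes after quantile normalization and 53.7% of 4479 after median-of-ratios scaling, so the balance between rising and falling genes depends on the scaling. Of the 9867 genes with at least 5 CPM, 5275 (53.5%) had groups that did not overlap, where chance gives 10%.

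Of 45 interferon-stimulated genes, 29 rose and none fell (35 rose adjusted over the list alone), with a median of 0.80 (camera adjusted p = 1.46e-13, and adjusted p = 0.316 with an estimated correlation). The antigen-presenting molecule H2-D1 rose from 66.7 ± 3.86 to 246 ± 32.3 CPM, and Gbp2 from 1.02 ± 0.232 to 25.9 ± 6.80 CPM. NF-kB and inflammatory genes were called up with 10 of 24 members higher and 1 lower (12 and 2 adjusted over the list alone; median 0.22, camera adjusted p = 0.0144, and adjusted p = 0.463 with an estimated correlation). The monocyte chemokine Ccl2 rose from 12.3 ± 2.23 to 76.0 ± 21.3 CPM while Cxcl5 fell from 24.7 ± 2.65 to 3.44 ± 1.71 CPM. Targets of the integrated stress response, driven by the transcription factor ATF4, were called up with 14 of 40 higher and 2 lower, also when adjusted over the list alone (median 0.32, camera adjusted p = 6.84e-04, and adjusted p = 0.613 with an estimated correlation). Among them the stress factor Atf3 rose by 1.68 and the pseudokinase Trib3 by 2.12. Of 35 replication-dependent histone genes, 21 rose and 2 fell (21 and 3 adjusted over the list alone; median 0.82, camera adjusted p = 6.96e-07, and adjusted p = 0.446 with an estimated correlation). Hist1h1c went from 7.10 ± 0.324 to 38.5 ± 3.56 CPM and Hist1h2bc from 10.1 ± 1.03 to 67.0 ± 9.34 CPM. Glycolysis and hypoxia genes were called up with 8 of 25 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.0375, and adjusted p = 0.640 with an estimated correlation), the vasodilator peptide Adm rising by 1.57. This call was lost without Total control 1 (adjusted p = 0.0974) or Total knockout 3 (0.126).

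Some genes of cell division, DNA repair and ribosome making were lower. Of 47 DNA replication genes, 17 fell and none rose (20 fell adjusted over the list alone; median -0.30, camera adjusted p = 8.13e-07, and adjusted p = 0.271 with an estimated correlation). Thymidylate synthase Tyms went from 137 ± 1.45 to 78.4 ± 7.45 CPM, and the histone chaperone subunit Chaf1b, from 78.7 ± 5.95 to 50.3 ± 2.26 CPM. Of 43 mitosis genes, 10 fell and none rose (13 fell adjusted over the list alone; median -0.30, camera adjusted p = 1.41e-05, and adjusted p = 0.293 with an estimated correlation), including the mitotic kinases Aurkb (-0.87) and Cdk1 (-0.48). DNA repair genes were called down with 14 of 32 lower and 2 higher (15 and 2 adjusted over the list alone; median -0.34, camera adjusted p = 3.93e-04, and adjusted p = 0.316 with an estimated correlation). The recombination mediator Brca2 went from 10.5 ± 1.05 to 4.71 ± 0.348 CPM and the repair scaffold Xrcc1 from 43.5 ± 3.74 to 25.3 ± 3.22 CPM. Ribosome biogenesis genes were called down with 8 of 40 lower and none higher (6 lower adjusted over the list alone; median -0.28, camera adjusted p = 1.41e-05, and adjusted p = 0.316 with an estimated correlation). The nucleolar methyltransferase Fbl fell by 0.54 on the log2 scale. RGG-motif and hnRNP genes, which encode RNA-binding proteins of a kind that Prmt1 methylates, had 9 of 39 lower and 2 higher, also when adjusted over the list alone (median -0.31, camera adjusted p = 3.93e-04, and adjusted p = 0.463 with an estimated correlation). In that list the splicing factor Srsf2 fell by 0.63 and the cold-inducible RNA-binding protein Cirbp fell by 0.83 on the log2 scale. Translation initiation factors had 5 of 41 lower and none higher (4 lower adjusted over the list alone; median -0.13, camera adjusted p = 0.0144, and adjusted p = 0.316 with an estimated correlation). The scaffold Eif4g3 fell from 22.2 ± 2.57 to 7.09 ± 0.703 CPM. The list's call was lost without Total knockout 1 (adjusted p = 0.0573) and after quantile normalization (0.0894), within 0.00640 to 0.316 over its alternatives. In the PRMT family, 4 of 8 members were lower and 1 higher, also when adjusted over the list alone. The deleted Prmt1 is 1 of these 4, beside Prmt3 (-0.40), Prmt6 (-0.35) and Prmt7, which overlaps Smpd3 (-0.74). The call (median -0.28, camera adjusted p = 0.0248, 0.271 with an estimated correlation) was not tested without Prmt1. It was lost without Total knockout 1 (0.0590) and after quantile normalization (0.0533). Without that library the medians were -0.18 for the PRMT family, -0.06 for initiation factors and -0.19 for ribosome biogenesis.

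Some markers of other cell types were also higher, at low levels. Macrophage markers had 5 of 11 higher and none lower (5 higher and 1 lower adjusted over the list alone; median 0.17, camera adjusted p = 0.0148, and adjusted p = 0.219 with an estimated correlation). Their median was 0.26 without Total knockout 2 and 0.09 without Total knockout 3. Endothelial markers had 5 of 11 higher (7 adjusted over the list alone; median 0.27, camera adjusted p = 0.00606, and adjusted p = 0.271 with an estimated correlation). Epithelial markers had 5 of 10 higher, also when adjusted over the list alone (median 0.36, camera adjusted p = 0.00191, and adjusted p = 0.219 with an estimated correlation). After quantile normalization these medians were 0.11, 0.17 and 0.23. The scavenger receptor Cd68 went from 1.09 ± 0.0889 to 3.65 ± 0.292 CPM, the receptor Flt1 from 0.428 ± 0.123 to 2.66 ± 0.382 CPM and keratin Krt14 from 0.566 ± 0.110 to 6.29 ± 0.829 CPM. The median mean level of a list member was 0.0819 CPM for the macrophage, 0.174 for the endothelial and 0.173 for the epithelial markers. None of the list calls in any comparison held with an estimated correlation between genes, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 21 of 31 lists here.

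The other lists did not pass in Total RNA. They had 12 higher and 4 lower of 31 p53 target genes (12 higher and 5 lower adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a, which rose from 4.30 ± 0.580 to 22.2 ± 1.51 CPM although the cells derive from p53-deficient mice. There were 8 higher and 3 lower of 28 apoptosis regulators (8 higher and 4 lower adjusted over the list alone). The extracellular matrix list had 11 higher and 5 lower of 39 and the osteoblast list 7 higher and 8 lower of 34, the same adjusted over the list alone. In the unfolded protein response list, with 4 higher and 6 lower of 28 (5 higher and 6 lower adjusted over the list alone), the median of 0.05 and the mean of 0.10 lay above 0 while camera's direction was down (adjusted p = 0.902). Cholesterol synthesis had 4 higher and 0 lower of 29 and cap-dependent oncogenes 5 higher and 4 lower of 18, also adjusted over the list alone, and oxidative phosphorylation 2 higher and 0 lower of 76 (none adjusted over the list alone). No member was called among 79 cytosolic ribosomal protein genes (median -0.10, camera adjusted p = 0.0633) or 31 proteasome genes (median -0.08, camera adjusted p = 0.0537). The ribosomal protein list passed without Total control 1 (0.0294), and the proteasome list without Total control 1 (0.0466), Total knockout 2 (0.0251) or Total knockout 3 (0.0386). Elongation factors had 0 higher and 1 lower of 10, snoRNA hosts 2 higher and 0 lower of 20, nuclear-retained transcripts 3 higher and 0 lower of 10. Osteoclast markers had 1 higher and 0 lower of 8, chondrocyte markers 1 higher and 1 lower of 10 and adipocyte and muscle markers 1 higher and 0 lower of 10. The nuclear-retained list passed without Total control 1 (0.0220) or Total knockout 3 (0.0234). Adjusted over the list alone these counts were 0 and 1, 1 and 0, 4 and 0, 1 and 0, 1 and 1, and 1 and 0. Myc (0.32, SE 0.18) and Eif4e (-0.26, SE 0.13) were not called, and Ccnd1, which overlaps Oraov1, rose from 127 ± 3.40 to 234 ± 61.5 CPM.

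The comparison of Light fractions asks which messages gained or lost share among RNA with few ribosomes. In knockout Light RNA 31 of 40 stress response, 20 of 25 glycolysis and 23 of 39 matrix genes rose, and 3 matrix genes fell. Of 79 ribosomal protein genes 47 fell and 3 rose, and none of these lists passed with an estimated correlation (adjusted p = 0.781 each). The transporter of antigenic peptides Tap2 rose from 3.57 ± 0.644 to 69.3 ± 25.3 CPM (log2 change 3.90, SE 0.30), C3 from 0.148 ± 0.137 to 24.2 ± 11.9 CPM and the antigen-presenting H2-K1 from 5.28 ± 0.790 to 66.8 ± 23.4 CPM. Also high were Msln (3.89, SE 0.31), the ADP-ribosyltransferase Parp10 (3.72, SE 0.24), Sfrp1 (3.52, SE 0.45) and the ferritin receptor Scara5 (3.47, SE 0.64). The glycosyltransferase Galnt11 fell from 17.6 ± 0.814 to 1.40 ± 0.190 CPM, the secreted protein Cthrc1 from 10.2 ± 0.787 to 0.682 ± 0.0956 CPM and Cxcl5 from 33.2 ± 3.80 to 3.32 ± 0.621 CPM. These genes had limma adjusted p-values of 4.72e-04 or lower. The median gene with at least 1 CPM shifted by 0.14 (log2), so list medians below are also given relative to that shift. Median Light changes rose with coding length, from -0.56 up to 300 nt to 0.42 over 2700 nt (-0.13 and 0.39 in Heavy).

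In Light RNA limma called 6926 of 17515 genes, 4702 higher and 2224 lower (67.9% higher), with 1033 and 289 changed at least 2-fold. The share called higher was 47.3% of 6479 genes after quantile normalization and 46.2% of 6913 after median-of-ratios scaling. Groups did not overlap for 6087 of 9469 genes with at least 5 CPM (64.3%), against 10% by chance.

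Interferon-stimulated genes had 32 of 45 members higher and none lower (35 adjusted over the list alone; median 0.91, relative 0.77; camera adjusted p = 3.90e-08, and adjusted p = 0.781 with an estimated correlation). H2-D1 went from 52.0 ± 2.28 to 253 ± 41.2 CPM. Stress response genes under ATF4 rose in 31 of 40 cases and none fell (33 and 1 adjusted over the list alone; median 0.87, relative 0.73; camera adjusted p = 5.26e-08, and adjusted p = 0.781 with an estimated correlation). Trib3 went from 28.3 ± 3.28 to 166 ± 68.4 CPM and Atf3 from 6.24 ± 0.652 to 21.8 ± 2.47 CPM. Of 25 glycolysis and hypoxia genes, 20 rose and none fell (21 adjusted over the list alone; median 0.78, relative 0.63; camera adjusted p = 3.04e-05, and adjusted p = 0.781 with an estimated correlation). The phosphofructokinase Pfkl went from 49.2 ± 5.50 to 171 ± 44.2 CPM, and hexokinase Hk1, from 23.8 ± 2.34 to 59.3 ± 3.35 CPM. The extracellular matrix list had 23 of 39 higher and 3 lower (25 and 3 adjusted over the list alone; median 0.68, relative 0.53; camera adjusted p = 0.00260, and adjusted p = 0.781 with an estimated correlation). The collagen hydroxylase P4ha2 went from 46.3 ± 6.42 to 149.6 ± 19.5 CPM and the crosslinking enzyme Loxl2 from 15.4 ± 2.77 to 63.1 ± 8.92 CPM. Cytosolic ribosomal protein messages moved the other way, 47 of 79 lower and 3 higher (51 and 3 adjusted over the list alone; median -0.56, relative -0.70; camera adjusted p = 1.83e-11, and adjusted p = 0.781 with an estimated correlation). Rpl36 fell from 1866 ± 174 to 922 ± 143 CPM. Oxidative phosphorylation had 33 of 76 lower and 10 higher (40 and 10 adjusted over the list alone; median -0.46, relative -0.60; camera adjusted p = 7.97e-07, and adjusted p = 0.781 with an estimated correlation), although its longer messages Sdha (1.34, SE 0.16) and Uqcrc1 (0.97, SE 0.13) rose. That list's call was lost with fry (adjusted p = 0.173) and when the dependence on coding length was removed (0.94), where its median was -0.05. There the ribosomal protein median was -0.19 and the matrix median 0.33, and after median-of-ratios scaling the matrix median was 0.45.

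No other list passed in Light RNA. Cholesterol synthesis had 14 higher and 1 lower of 29 (16 higher and 2 lower adjusted over the list alone; median 0.66, relative 0.52, camera adjusted p = 0.0552). The proteasome had 14 higher and 1 lower of 31, also when adjusted over the list alone (median 0.30, relative 0.16, 0.0713). Cholesterol synthesis passed without Light control 2 (0.0430), Light knockout 2 (0.0215) or Light knockout 3 (0.0116), and the proteasome without Light control 1 (0.0240) or Light knockout 3 (0.00519). Replication-dependent histones had 18 higher and 7 lower of 35 (19 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.106). Hist1h1c went from 12.9 ± 0.828 to 62.1 ± 4.95 CPM. Epithelial markers had 7 of 10 higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.0654). Histones passed without Light control 2 (0.0430), Light knockout 1 (0.0326) or Light knockout 3 (0.0365), and epithelial markers without Light control 2 (0.0435). Macrophage and endothelial markers had 5 of 11 higher each, with Cd68 from 0.815 ± 0.0335 to 2.96 ± 0.296 CPM and Krt14 from 0.403 ± 0.0593 to 4.60 ± 0.426 CPM. Initiation factors had 16 higher and 5 lower of 41 (16 higher and 7 lower adjusted over the list alone): Eif3c and Eif3h, subunits of the factor that joins messages to the small ribosomal subunit, rose by 1.29 and 0.60. Elongation factors had 3 higher and 1 lower of 10 (3 higher and 3 lower adjusted over the list alone; median -0.23, relative -0.38, camera adjusted p = 0.467), with Eef2 and Eef1a1 at 1.08 and 0.67. Mcl1, a survival factor of the Bcl-2 family, rose from 149 ± 8.99 to 192 ± 13.9 CPM, a call lost after median-of-ratios scaling (limma adjusted p = 0.237).

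The comparison of Heavy fractions asks which messages gained or lost share among RNA on larger polysomes. In Heavy RNA of knockout cells 35 of 45 interferon-stimulated, 21 of 40 stress response and 22 of 39 matrix genes rose, while 0, 1 and 5 fell. Lower were 32 of 79 ribosomal protein, 12 of 31 proteasome and 18 of 47 DNA replication genes, with 0, 1 and 6 higher, and none of these lists passed with an estimated correlation (adjusted p = 0.493 each). C3 rose from 0.221 ± 0.194 to 29.5 ± 20.8 CPM (log2 change 4.45, SE 0.39) and Parp10 from 3.36 ± 0.522 to 56.0 ± 24.7 CPM. The membrane glycoprotein Gpnmb rose by 3.36 and Ly6a from 4.95 ± 0.769 to 58.5 ± 13.3 CPM. Gbp2 (3.71, SE 0.30) and Msln (3.71, SE 0.31) were also among the highest. Avpr1a fell from 15.6 ± 0.301 to 1.18 ± 0.310 CPM, and Igfbp7 (-3.21, SE 0.10) and Prr5l, a partner of mTOR complex proteins (-2.63, SE 0.17), fell as well. Prl2c5 (-3.07, SE 0.32) and Prl2c1 (-2.62, SE 0.27) fell within the proliferin family. Prmt1 itself was the member of the PRMT family with the lowest change (-1.88, SE 0.21). Each of these had a limma adjusted p of 7.87e-06 or lower.

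Here limma called 5061 of 17515 genes, 3242 higher and 1819 lower (64.1% higher), with 747 and 232 changed at least 2-fold. The share called higher was 49.1% of 5158 genes after quantile normalization and 44.6% of 5707 after median-of-ratios scaling. Groups did not overlap for 4286 of 9198 genes with at least 5 CPM (46.6%), against 10% by chance. Fitted on the Heavy libraries alone, with no spread borrowed from the other fractions, the count was 2976.

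Of 45 interferon-stimulated genes, 35 rose and none fell (37 adjusted over the list alone; median 0.95, relative 0.90; camera adjusted p = 3.32e-13, and adjusted p = 0.493 with an estimated correlation). H2-D1 went from 103 ± 10.3 to 311 ± 26.6 CPM and Xaf1 from 1.86 ± 0.436 to 24.6 ± 5.19 CPM. ATF4 stress targets had 21 of 40 higher and 1 lower (24 and 1 adjusted over the list alone; median 0.62, camera adjusted p = 3.68e-05, and adjusted p = 0.493 with an estimated correlation). Atf3 went from 4.96 ± 0.238 to 16.1 ± 1.92 CPM. Histones had 20 of 35 higher and 1 lower (21 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 2.35e-05, and adjusted p = 0.493 with an estimated correlation). Hist1h2bc went from 4.54 ± 0.666 to 32.5 ± 9.27 CPM. The matrix list had 22 of 39 higher and 5 lower (26 and 5 adjusted over the list alone; median 0.57, camera adjusted p = 7.30e-04, and adjusted p = 0.493 with an estimated correlation). Fibronectin Fn1 rose from 338 ± 83.1 to 1474 ± 318 CPM and the crosslinking enzyme Loxl1 fell from 358 ± 53.8 to 125 ± 15.1 CPM. Glycolysis and hypoxia had 12 of 25 higher and none lower, also when adjusted over the list alone (median 0.38, camera adjusted p = 0.00439, and adjusted p = 0.493 with an estimated correlation). NF-kB and inflammatory genes had 8 of 24 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.0197, and adjusted p = 0.493 with an estimated correlation), a call lost without Heavy knockout 1 (adjusted p = 0.0905). Endothelial markers had 5 of 11 higher (median 0.16, camera adjusted p = 0.0127, and adjusted p = 0.398 with an estimated correlation). Epithelial markers had 5 of 10 higher (median 0.29, camera adjusted p = 0.00786, and adjusted p = 0.398 with an estimated correlation). Both counts were the same adjusted over the list alone, and Krt14 went from 0.721 ± 0.0994 to 6.10 ± 2.67 CPM. The endothelial call was lost when the dependence on coding length was removed (0.356). There the endothelial median was 0.02 and the matrix median 0.30. Medians were 0.20 for glycolysis and 0.08 for NF-kB genes after median-of-ratios scaling, and 0.37 for histones after quantile normalization. Without Heavy knockout 1 the stress response was at 0.38, NF-kB genes at 0.10 and endothelial markers at 0.24 (0.24 without Heavy control 2).

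Cytosolic ribosomal protein messages were lower in 32 of 79 cases and higher in none (46 lower adjusted over the list alone; median -0.46, relative -0.51; camera adjusted p = 3.32e-13, and adjusted p = 0.493 with an estimated correlation). Rps4x went from 2166 ± 206 to 1453 ± 218 CPM. Proteasome genes had 12 of 31 lower and 1 higher (13 and 2 adjusted over the list alone; median -0.26, camera adjusted p = 2.15e-05, and adjusted p = 0.493 with an estimated correlation). The ATPase subunit Psmc4 went from 283 ± 11.8 to 209.8 ± 20.1 CPM. DNA replication had 18 of 47 lower and 6 higher (20 and 8 adjusted over the list alone; median -0.21, camera adjusted p = 0.00435, and adjusted p = 0.493 with an estimated correlation). Tyms went from 204 ± 14.3 to 103 ± 20.4 CPM. Initiation factors had 14 of 41 lower and 3 higher (16 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.00439, and adjusted p = 0.398 with an estimated correlation). Elongation factors had 3 of 10 lower and 1 higher (4 and 1 adjusted over the list alone; median -0.46, camera adjusted p = 0.0134, and adjusted p = 0.398 with an estimated correlation). The guanine exchange factor subunits Eif2b1 and Eif2b3 fell by 0.65 and 0.66, and the elongation factor subunit Eef1b2 fell by 0.84 on the log2 scale. Those initiation and elongation calls were lost after quantile normalization (adjusted p = 0.0749 and 0.117). The PRMT family, Prmt1 included, had 3 of 8 lower and 1 higher (3 and 2 adjusted over the list alone). Its median was -0.28 (camera adjusted p = 0.0158, 0.398 with an estimated correlation). Its call was lost after quantile normalization (0.0579) and with the coding-length trend removed (0.0513). Without Heavy knockout 1 the medians were -0.19 for ribosomal proteins, -0.13 for initiation factors, -0.19 for elongation factors and -0.14 for the PRMT family. After median-of-ratios scaling they were -0.40 for initiation factors, -0.45 for the PRMT family, -0.44 for the proteasome and -0.38 for DNA replication.

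Each of the remaining Heavy calls was lost without some single library. Oxidative phosphorylation had 12 of 76 lower and 1 higher (none and 1 adjusted over the list alone; median -0.25, camera adjusted p = 1.65e-05, and adjusted p = 0.563 with an estimated correlation). That call was lost without Heavy knockout 1 (adjusted p = 0.116), without all knockout libraries numbered 1 (0.0933) and with fry (0.157). RGG-motif and hnRNP genes had 12 of 39 lower and 5 higher (14 and 6 adjusted over the list alone; median -0.16, camera adjusted p = 0.0127, and adjusted p = 0.564 with an estimated correlation). This result was lost without Heavy control 3 (0.0706) or Heavy knockout 3 (0.199), after quantile normalization (0.146), with the coding-length trend removed (0.0535) and with fry (0.157). Mitosis genes had 10 of 43 lower and 2 higher, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.0177, and adjusted p = 0.493 with an estimated correlation). The list lost its call without Heavy control 3 (0.0529) or Heavy knockout 3 (0.0717), after quantile normalization (0.0579) and with fry (0.11). Ribosome biogenesis had 11 of 40 lower and 5 higher (12 and 5 adjusted over the list alone; median -0.06, camera adjusted p = 0.0242, and adjusted p = 0.564 with an estimated correlation). Its call was lost without Heavy control 3 (0.0948) or Heavy knockout 3 (0.259), after quantile normalization (0.185) and with fry (0.157). The medians were small and moved by over 1.5 times without single libraries. For oxidative phosphorylation they were -0.05 and -0.43 without Heavy knockout 1 or 3. For RGG-motif and hnRNP genes they were -0.28 and -0.09 without Heavy control 1 or 3, and -0.26 and -0.04 without Heavy knockout 1 or 3. For mitosis they were -0.03 and -0.01 without Heavy control 2 or 3, and -0.04 without Heavy knockout 1 or 3. For ribosome biogenesis they were -0.14 and -0.02 without Heavy control 1 or 3, and -0.11 and -0.04 without Heavy knockout 1 or 3. After median-of-ratios scaling these 4 lists were at -0.42, -0.34, -0.23 and -0.24. With the coding-length trend removed mitosis was at -0.22 and ribosome biogenesis at -0.22, and after quantile normalization mitosis was at -0.16. Single members still differed, with the mitotic kinase Aurkb from 180.4 ± 3.48 to 87.6 ± 11.2 CPM, the ribosome assembly factor Rrs1 from 201 ± 3.96 to 123 ± 12.4 CPM and Cirbp from 42.1 ± 5.08 to 19.2 ± 4.20 CPM. Nuclear-retained transcripts had 5 of 10 higher (median 0.36, camera adjusted p = 0.0991), with Neat1, the scaffold of paraspeckles, from 8.12 ± 0.239 to 23.3 ± 3.82 CPM, and macrophage markers 4 of 11.

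**Figure D2:**
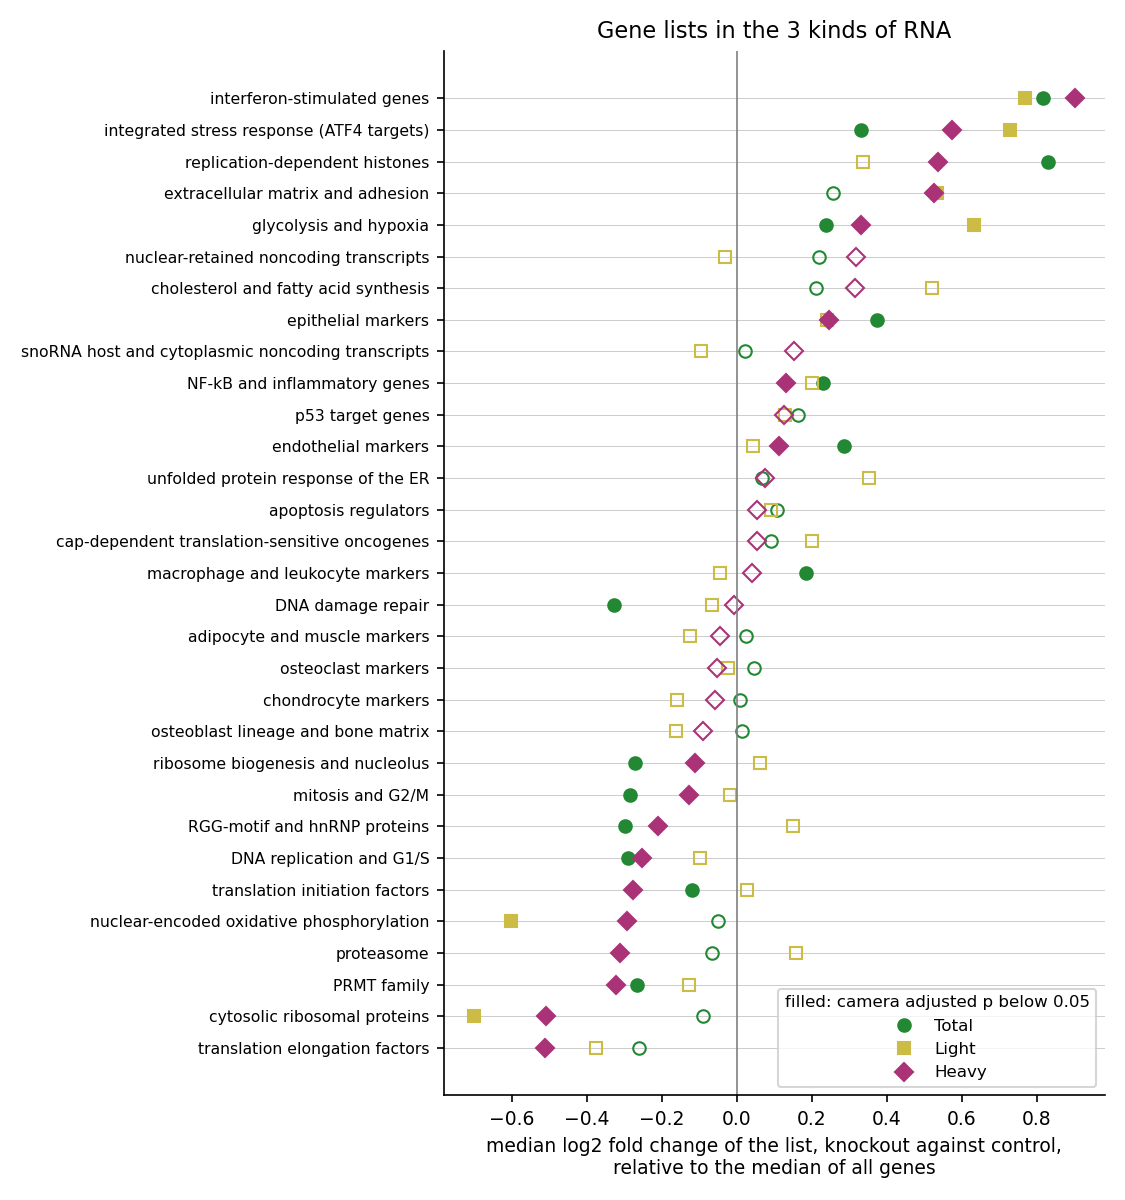
Median log2 change of each of the 31 gene lists, knockout against control cells, in Total, Light and Heavy RNA. Each is given less the median of all genes with a mean of at least 1 CPM. Filled symbols mark lists that passed camera with its preset correlation, and none passed with an estimated correlation. Interferon-stimulated genes lie at 0.82, 0.77, 0.90 and ribosomal protein genes at -0.09, -0.70, -0.51.

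Across fractions 1881 genes were higher in Total, Light and Heavy RNA and 847 were lower in all of them. Total and Light shared 2300 higher calls where independent lists would share 757, and 1117 lower calls where they would share 230. Total and Heavy shared 2027 higher (522 if independent) and 1199 lower (188), and Light and Heavy 2671 higher (870.3) and 1055 lower (231). The fractions share no libraries. Yet knockout libraries of the same number deviated together in Heavy and Light (correlation 0.263 to 0.641) and in Light and Total (0.461 to 0.648). Independence is thus not met, and the counts for independent lists are a rough scale only. Genes that rose in every fraction include H2-D1, Gbp2, Cdkn1a and Atf3, and the pro-apoptotic Bcl2l11, which rose by 1.19, 1.03 and 1.26 in Total, Light and Heavy RNA.

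The comparison of Heavy with Light RNA in control cells describes what each pool held before any loss of Prmt1. Higher in Heavy RNA were 27 of 31 proteasome, 35 of 39 RGG-motif and hnRNP and 17 of 25 glycolysis genes, with 4 glycolysis genes lower. Higher in Light RNA were 33 of 35 histone genes and 17 of 20 snoRNA host and cytoplasmic noncoding transcripts, and none of these lists passed with an estimated correlation (adjusted p = 0.252 to 0.373). The membrane-binding protein Anxa5 was higher in Heavy, from 162 ± 10.4 to 714 ± 28.1 CPM (log2 difference 2.13, SE 0.18), as were the RNA helicase Eif4a3 (2.11, SE 0.12), the methylation-cycle enzyme Ahcy (2.00, SE 0.15) and Hnrnpa2b1 (2.06, SE 0.18). The actin-sequestering thymosins Tmsb10 and Tmsb4x were lower in Heavy (-3.34, SE 0.22, and -3.26, SE 0.21), as were the copper chaperone Atox1 (-3.15, SE 0.24), Rps29 (-3.15, SE 0.20) and the respiratory subunit Cox8a (-3.13, SE 0.23). Each had a limma adjusted p of 6.33e-08 or lower. In control cells Prmt1 was higher in Heavy than in Light RNA (0.70, SE 0.21, adjusted p = 0.0119). Of 17515 genes, limma called 8879, 4128 higher and 4751 lower in Heavy (46.5% higher), and groups did not overlap for 7589 of 9236 genes (82.2%, against 10% by chance). The median difference followed coding length: it was -2.41 for the 173 genes of up to 300 nt, -1.44 from 300 to 600 nt, -0.08 from 600 to 1200 nt, 0.49 from 1200 to 1800 nt and 0.32 above 2700 nt.

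Proteasome genes were higher in Heavy in 27 of 31 cases and lower in none (median 1.28, camera adjusted p = 1.85e-12, and adjusted p = 0.252 with an estimated correlation). RGG-motif and hnRNP genes were higher in 35 of 39 (median 1.09, camera adjusted p = 2.91e-11, and adjusted p = 0.252 with an estimated correlation). Ribosome biogenesis genes were higher in 30 of 40 with 1 lower (median 0.88, camera adjusted p = 2.52e-09, and adjusted p = 0.252 with an estimated correlation). These counts were the same adjusted over the list alone. DNA replication had 33 of 47 higher and 5 lower (34 and 5 adjusted over the list alone; median 0.79, camera adjusted p = 8.62e-08, and adjusted p = 0.252 with an estimated correlation). The polymerase clamp Pcna went from 148 ± 11.8 to 564 ± 13.9 CPM. Initiation factors had 24 of 41 higher and 9 lower, also when adjusted over the list alone (median 0.62, camera adjusted p = 1.91e-04, and adjusted p = 0.252 with an estimated correlation), the cap-binding repressor Eif4ebp1 at -2.38 being among the lowest. Glycolysis had 17 of 25 higher and 4 lower (18 and 4 adjusted over the list alone; median 1.19, camera adjusted p = 7.24e-05, and adjusted p = 0.373 with an estimated correlation). Ldha went from 680.0 ± 58.3 to 2549 ± 89.1 CPM. Mitosis, stress response, unfolded protein response, matrix, cholesterol and DNA repair lists were also called higher, with medians of 0.52, 0.59, 0.59, 0.37, 0.68 and 0.34 (adjusted p = 9.90e-05, 0.00132, 0.0177, 0.00364, 0.00439 and 0.00193; adjusted p = 0.349, 0.578, 0.578, 0.570, 0.624 and 0.435 with an estimated correlation). Their members had 24 higher and 5 lower of 43, 25 higher and 6 lower of 40, 15 higher and 5 lower of 28, 16 higher and 2 lower of 39, 16 higher and 2 lower of 29 and 16 higher and 2 lower of 32 called (24 and 5, 26 and 7, 16 and 6, 16 and 2, 17 and 3, 16 and 2 adjusted over the list alone). The DNA strand-break repair scaffold Xrcc1 was at 1.22. The matrix median was 0.58 after quantile normalization. The PRMT family had 6 of 8 higher and 1 lower, also when adjusted over the list alone (median 0.63, camera adjusted p = 0.0444, and adjusted p = 0.314 with an estimated correlation). The call was lost without Heavy control 1 (0.0706), Heavy control 2 (0.0505) or Light control 3 (0.0678) and after quantile normalization (0.0671).

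Lower in Heavy were 33 of 35 histone genes and none higher (median -1.26, camera adjusted p = 1.40e-09, and adjusted p = 0.373 with an estimated correlation), the same adjusted over the list alone. So were 17 of 20 snoRNA host and cytoplasmic noncoding transcripts (18 adjusted over the list alone; median -1.93, camera adjusted p = 1.05e-07, and adjusted p = 0.314 with an estimated correlation). Snhg3 went from 63.8 ± 8.28 to 7.93 ± 0.835 CPM. Oxidative phosphorylation had 56 of 76 lower and 13 higher (58 and 14 adjusted over the list alone; median -1.55, camera adjusted p = 1.06e-07, and adjusted p = 0.570 with an estimated correlation). Ribosomal proteins had 54 of 79 lower and 15 higher (55 and 16 adjusted over the list alone; median -1.12, camera adjusted p = 2.10e-05, and adjusted p = 0.624 with an estimated correlation). The long message Rpl3 (1.81) and the short Rpl39 (-3.09) lay at opposite ends. Nuclear-retained transcripts had 6 of 10 lower, also when adjusted over the list alone (median -0.87, camera adjusted p = 0.0444, and adjusted p = 0.449 with an estimated correlation). It was lost without Heavy control 2 (0.0619) or Light control 3 (0.0678, median -0.56). With the coding-length trend removed, the ribosomal protein median became 0.23 (adjusted p = 0.0137) and the histone median 0.26 (0.0337), both reversed, and the oxidative phosphorylation median -0.08 (0.93). The unfolded protein response (0.0581), matrix (0.0906), DNA repair (0.122) and PRMT family (0.452) calls were lost, the medians of the last 2 being 0.14 and 0.33, and the mitosis median was 0.29.

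**Figure D3:**
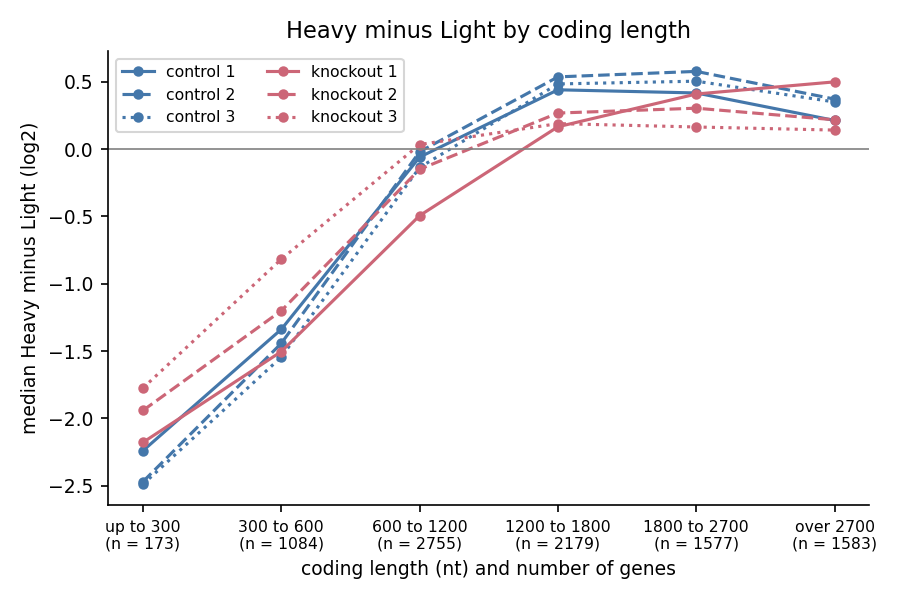
Median log2 difference between Heavy and Light RNA in bins of coding length (nt), for control and knockout cells; points are the medians of Heavy minus Light libraries of the same number, 3 per genotype, joined by lines. Short coding regions lie far under 0 in both genotypes, at a mean of -2.40 in control and -1.97 in knockout cells up to 300 nt.

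The interaction of Heavy with Light asks whether loss of Prmt1 moved messages between the pools, as the difference between the Heavy and the Light effects. Most genes called moved toward Light, Prmt1 among them, as did 9 of 31 proteasome and 6 of 41 initiation factor genes. Neither list passed with an estimated correlation (adjusted p = 0.375 each). The lean of the gene calls depends on the fit: with libraries of the same number as a block 10 genes were called, 9 toward Heavy and only Prmt1 toward Light. Prmt1 itself shifted by -1.68 (SE 0.30, limma adjusted p = 0.0194), since Heavy exceeded Light by 0.69, 0.63 and 0.76 (log2) in the control libraries of the same number and fell short of it in the knockout libraries, at -1.35, -0.91 and -0.69. Galnt11, although lower in every knockout pool, shifted toward Heavy (1.18, SE 0.14, adjusted p = 0.00691, 4.67e-04 to 0.0924 over its alternatives), and so did Ccdc142 (1.03, SE 0.15, 0.00852, 0.00102 to 0.0605). Shifts toward Light included the milk fat globule protein Mfge8 (-1.17, SE 0.17, 0.0102, 0.00244 to 0.0605) and the centromere protein Cenpt, which overlaps Tsnaxip1 (-1.13, SE 0.17, 0.0116, 0.00471 to 0.0605). They also included smooth muscle actin Actg2 (-1.12, SE 0.18, 0.0134, 0.00485 to 0.0605), the matrix proteoglycan Bgn (-0.96, SE 0.15, 0.0134, 1.84e-04 to 0.0786) and the purine enzyme Impdh2, which overlaps Ndufaf3 (-1.05, SE 0.18, 0.0140, 0.00537 to 0.0733). Further shifts toward Light were those of the ubiquitin receptor Psmd4 (-0.96, SE 0.17, 0.0187, 0.00485 to 0.0817), lactate dehydrogenase Ldha (-0.90, SE 0.16, 0.0194, 0.00403 to 0.0817) and the initiation factors Eif3h (-0.75, SE 0.14, 0.0197, 0.00534 to 0.0859) and Eif2b5 (-0.69, SE 0.14, 0.0212, 0.00601 to 0.133).

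These calls are fragile. The Prmt1 call was lost without Heavy control 1, 2 or 3 (adjusted p = 0.0533, 0.0539 and 0.0529) or Light control 2 or 3 (0.0591 and 0.068), and with the 12 libraries of the comparison alone (0.0817), within 0.000574 to 0.0817 over its alternatives. Galnt11 and Ccdc142 were called whichever library was left out. Without Light control 3 the calls of Mfge8 (0.0512), Cenpt (0.0532), Actg2 (0.0545), Bgn (0.0545) and Impdh2 (0.0611) were lost, and without Light control 2 that of Impdh2 (0.0552). Psmd4 was not called without Heavy control 1 (0.0533), Heavy control 2 (0.0539), Light control 2 (0.0647) or Light control 3 (0.068). Ldha, Eif3h and Eif2b5 were not called without any 1 of Heavy control 1 (0.0533, 0.054 and 0.0554), Heavy control 2 (0.0534, 0.0539 and 0.0539), Heavy control 3 (0.0529, 0.0529 and 0.0564), Light control 2 (0.0647, 0.0654 and 0.0654) or Light control 3 (0.068 each). Eif2b5 was also lost without Light knockout 1 (0.0515).

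In all, limma called 503 of 17515 genes, 62 toward Heavy and 441 toward Light (12.3% toward Heavy), with 2720 at an unadjusted p under 0.05. The share toward Heavy was 28.9% of 152 genes after quantile normalization and 53.1% of 49 after median-of-ratios scaling, so the lean toward Light depends on the scaling. Libraries of the same number deviated together in Heavy and Light, and the 10 genes called with that pairing as a block were Prmt1 (blocked adjusted p = 0.0403), Galnt11 (0.0345), Mtus2 (0.041, chosen after its values were seen) and 7 gene models without a name, 5 of them with nearly the same values. The other genes named above lost their call under the block, at 0.0605 to 0.0718. The count was 40 without Heavy control 1, 29 without Heavy control 2 and 36 without Heavy control 3. It was 2011 without Heavy knockout 1, 297 without Heavy knockout 2 and 167 without Heavy knockout 3. It fell to 18 without Light control 2, 7 without Light control 3 and 87 without Light knockout 1, and rose to 1872 without all knockout libraries numbered 1. With the 12 libraries of the comparison alone it was 8, and with the coding-length trend removed 23.

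Proteasome genes shifted toward Light in 9 of 31 cases and toward Heavy in none (20 adjusted over the list alone; median -0.54, camera adjusted p = 2.61e-14, and adjusted p = 0.375 with an estimated correlation). Initiation factors did so in 6 of 41 cases (13 adjusted over the list alone; median -0.31, camera adjusted p = 0.00101, and adjusted p = 0.375 with an estimated correlation) and RGG-motif and hnRNP genes in 3 of 39 (6 adjusted over the list alone; median -0.35, camera adjusted p = 1.17e-05, and adjusted p = 0.742 with an estimated correlation). Ribosome biogenesis had 3 of 40 toward Light (6 adjusted over the list alone; median -0.22, camera adjusted p = 0.00261, and adjusted p = 0.742 with an estimated correlation). DNA replication had 2 of 47 toward Light (5 adjusted over the list alone; median -0.27, camera adjusted p = 0.00241, and adjusted p = 0.742 with an estimated correlation). These 5 lists passed whichever library was left out, but some medians shrank by over 1.5 times. With the coding-length trend removed ribosome biogenesis was at -0.09 and DNA replication at -0.14, after quantile normalization these were -0.14 and -0.16 and initiation factors -0.21, and without all knockout libraries numbered 1 the proteasome was at -0.34. Glycolysis had 4 of 25 toward Light (8 adjusted over the list alone; median -0.49, camera adjusted p = 0.0144, and adjusted p = 0.742 with an estimated correlation). That call was lost without Heavy knockout 2 (0.0778), Heavy knockout 3 (0.0628) or Light knockout 1 (0.0783). Stress response targets had 1 of 40 each way (1 and 2 adjusted over the list alone; median -0.36, camera adjusted p = 0.0206, and adjusted p = 0.789 with an estimated correlation). This result was lost without Heavy knockout 2 (0.154), Heavy knockout 3 (0.234), Light control 3 (0.09) or Light knockout 1 (0.295). The unfolded protein response had 3 of 28 toward Light (4 adjusted over the list alone; median -0.35, camera adjusted p = 0.0436, and adjusted p = 0.742 with an estimated correlation). The list lost its call without Heavy control 2 (0.094) or 3 (0.0749), Heavy knockout 2 (0.114) or 3 (0.171), Light control 1 (0.061) or 3 (0.073), or Light knockout 1 (0.295). Without Light knockout 1 the glycolysis median was -0.27 and the stress response median -0.20. The latter was -0.56 without Heavy knockout 1 and -0.22 without Heavy knockout 2 or 3. The medians were -0.27 for glycolysis, -0.21 for the stress response and -0.15 for the unfolded protein response with the coding-length trend removed.

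Toward Heavy, histones had a median of 0.21 with no member called (camera adjusted p = 0.00240, and adjusted p = 0.742 with an estimated correlation; lost without Heavy control 3 at 0.0749, Heavy knockout 3 at 0.0862 or Light knockout 3 at 0.0546). Their median was 0.13 without Heavy control 3, 0.37 without Heavy knockout 1 and 0.12 without Heavy knockout 3, and it turned to -0.09 (0.00937) when the coding-length trend was removed. Histone members with the lowest p were Hist1h3c (0.49, SE 0.17) and Hist2h2ac (-0.63, SE 0.26). The snoRNA host list had a median of 0.27 with no member called (camera adjusted p = 0.00543, and adjusted p = 0.742 with an estimated correlation; lost without Light knockout 1 at 0.385), with Rmrp at 0.31, SE 0.16. That median was 0.42 and 0.18 without Heavy knockout 1 or 2, and 0.05 and 0.46 without Light knockout 1 or 3. Without all knockout libraries numbered 1 the snoRNA host median was 0.17 and the histone median 0.33. Ribosomal protein and oxidative phosphorylation lists did not pass (medians 0.13 and 0.19, camera adjusted p = 0.468 and 0.169). The ribosomal protein list passed toward Heavy without Heavy knockout 1 (7.77e-10) and oxidative phosphorylation without Heavy control 1 (0.0320), Heavy knockout 1 (7.77e-10) or Light knockout 2 (0.0175), while both passed toward Light with the coding-length trend removed, at -0.21 and -0.17. Cholesterol synthesis (median -0.36, camera adjusted p = 0.169, and adjusted p = 0.925 with an estimated correlation) passed with the block (0.00228) and without Heavy knockout 1 (1.19e-04) or Light knockout 3 (0.0416). With fry, only the proteasome and initiation factor lists passed among the called lists (0.00538 each).

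**Figure D4:**
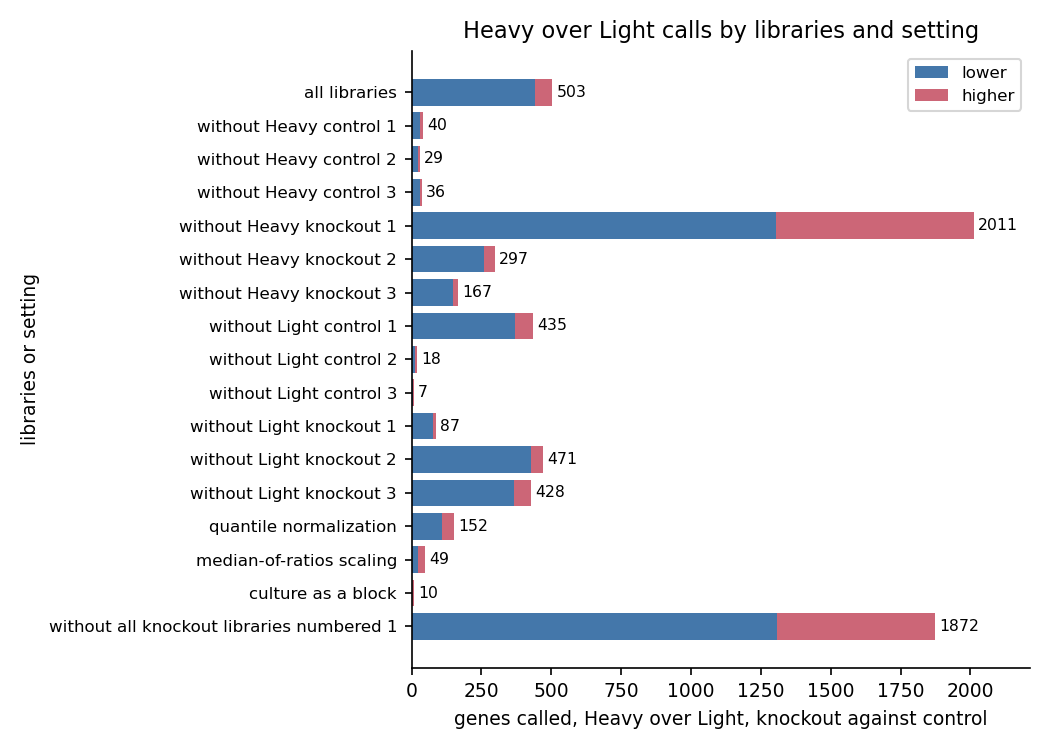
Genes called in the Heavy over Light interaction, knockout against control cells, by setting; bars count genes shifted toward Heavy (higher) and toward Light (lower). The count is 503 with all libraries, 10 with the replicate number as a block, 49 after median-of-ratios scaling and 1872 without the knockout libraries numbered 1.

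The interaction of Heavy with Total asks whether Heavy share changed beyond the change in abundance. The medians of ribosomal protein and proteasome messages lay under 0 and those of matrix and DNA repair messages above 0, but none of these lists passed with an estimated correlation (adjusted p = 0.894 to 0.950) and 2 genes were called. Ribosomal proteins had a median of -0.39 over 79 genes (camera adjusted p = 1.34e-16, and adjusted p = 0.950 with an estimated correlation), with Rps4x at -0.52, SE 0.16 and Rpl5, which overlaps Fam69a, at -0.50, SE 0.17. Their median was -0.08 without Heavy knockout 1 and -0.04 without all knockout libraries numbered 1. The proteasome had a median of -0.18 (camera adjusted p = 2.09e-04, and adjusted p = 0.950 with an estimated correlation). Without Heavy knockout 1 that was -0.11. Oxidative phosphorylation had a median of -0.19 (camera adjusted p = 4.16e-06, and adjusted p = 0.950 with an estimated correlation), which turned to 0.07 (adjusted p = 0.763) without Heavy knockout 1 and to 0.10 (0.500) without all knockout libraries numbered 1, and was -0.36 without Heavy knockout 3. The matrix list had a median of 0.30 with 5 of 39 higher adjusted over the list alone (camera adjusted p = 3.82e-06, and adjusted p = 0.896 with an estimated correlation); fibrillar collagen Col5a1 was at 1.00, SE 0.27. DNA repair had a median of 0.24 (camera adjusted p = 2.95e-05, and adjusted p = 0.894 with an estimated correlation), with Brca1 at 0.58, SE 0.18. The matrix median was 0.50 without Heavy knockout 3, and that of DNA repair 0.39 without Heavy knockout 2, 0.38 without Heavy knockout 3 and 0.36 without Total control 3. They were 0.17 and 0.09 with the coding-length trend removed. After median-of-ratios scaling DNA repair was at 0.14, the proteasome at -0.30 and oxidative phosphorylation at -0.31. No member of these lists was called over all genes.

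Ribosome biogenesis (median 0.16, camera adjusted p = 0.0120, and adjusted p = 0.950 with an estimated correlation) lost its call without Heavy knockout 2 (0.154) or Total knockout 1 (0.553), without all knockout libraries numbered 1 (0.808) and after median-of-ratios scaling (0.176). Mitosis (median 0.17, camera adjusted p = 0.0290, and adjusted p = 0.950 with an estimated correlation) lost it without Heavy control 1 (0.112), Heavy knockout 2 (0.154), Total control 1 (0.277) or Total knockout 1 (0.553), without all knockout libraries numbered 1 (0.500) and after median-of-ratios scaling (0.213). Macrophage markers (median -0.13, camera adjusted p = 0.0137, and adjusted p = 0.283 with an estimated correlation) lost it without Heavy knockout 3 (0.0906) or Total control 1 (0.0762) and after quantile (0.103) or median-of-ratios scaling (0.176), with Cd68 at -0.47, SE 0.17. The ribosome biogenesis median was 0.09 without Heavy control 1 and 0.24 without Total control 3. That of mitosis was 0.11 and 0.26 without Total control 1 or 3. For macrophage markers it was -0.08 without Heavy control 1, -0.03 without Heavy knockout 2 or 3, and -0.02 and -0.24 without Total knockout 1 or 2. The medians of these 3 lists were 0.04, 0.05 and -0.08 after median-of-ratios scaling, 0.06, 0.02 and -0.29 with the coding-length trend removed, and 0.08, 0.11 and -0.04 without all knockout libraries numbered 1. After quantile normalization mitosis was at 0.10 and macrophage markers at -0.04. With the coding-length trend removed the proteasome (0.0534), DNA repair (0.0534) and mitosis (0.073) calls were lost, and with fry only the macrophage list passed among the called lists (0.0077). Prmt1 was not called in this interaction (-1.16, SE 0.30, limma adjusted p = 0.251), but it was without all knockout libraries numbered 1 (-0.90, adjusted p = 0.0484), within 0.0484 to 0.601 over its alternatives. In all, limma called 2 of 17515 genes, with 1388 at an unadjusted p under 0.05 and 0 called by voom. They are the channel subunit Cngb1 (-1.02, SE 0.15, adjusted p = 0.0295) and the gene model 4833412C05Rik (1.13, SE 0.12, 7.75e-04), named after their values were seen, with means of 0.609 and 0.718 CPM. The Cngb1 call was lost without Heavy control 1, 2 or 3 (0.0916, 0.0867 and 0.153), Heavy knockout 1, 2 or 3 (0.110, 0.121 and 0.0998), Total control 1, 2 or 3 (0.0968, 0.0908 and 0.0732) or Total knockout 2 (0.0660). Only 1 gene was called without Heavy control 1, 2 or 3, Heavy knockout 1, 2 or 3, or Total control 1 or 2, and 3 without Total knockout 1 and 9 without Total knockout 3.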

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

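All of the checks named in this part were chosen after the result was seen. The results below were marked because the effect of the knockout differed between fractions, so they do not follow from the change within either fraction alone. In Heavy over Light 503 genes were called and in Heavy over Total 2. For Prmt1 the difference was -1.68, for Galnt11 1.18 and for Ccdc142 1.03. It was -1.17 for Mfge8, -1.13 for Cenpt, -1.12 for Actg2, -0.96 for Bgn, -1.05 for Impdh2, -0.96 for Psmd4, -0.90 for Ldha, -0.75 for Eif3h and -0.69 for Eif2b5. Among gene lists the medians were -0.31 for translation initiation factors, -0.22 for ribosome biogenesis, -0.35 for RGG-motif and hnRNP genes, -0.27 for DNA replication and -0.36 for the integrated stress response. They were -0.35 for the unfolded protein response, -0.49 for glycolysis, -0.54 for the proteasome, 0.21 for histones and 0.27 for snoRNA hosts. None of these lists passed with an estimated correlation (adjusted p = 0.375 to 0.789). The histone median turned to -0.09 with the coding-length trend removed, and that of snoRNA hosts was 0.05 without Light knockout 1.

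Heavy and Light RNA differed less in knockout than in control cells, with a slope on the mean control difference of 0.600 to 0.813 in knockout pairs of libraries and, for each control pair against the other 2, of 0.865 to 1.07 over 9389 coding genes. Carry-over between the pools, or a shifted boundary, predicts the same for noncoding RNA, and the highest noncoding slope of a knockout pair was 0.775, under the lowest control slope of 0.853. Fewer ribosomes on coding messages alone would leave noncoding RNA unchanged, but the 0.775 cannot decide, as noncoding genes may share reads with coding ones. No single knockout culture explains the smaller difference: with any 1 left out both other coding slopes lay under every control slope, with a mean of at most 0.783. The shift toward Light of messages rich in control Heavy RNA could thus be technical. Gradient traces that would tell are not given here.

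The knockout libraries numbered 1 lay apart from their groups in all fractions. A fault in a single library would leave the deviations of the 3 fractions unrelated, but they correlated at 0.565, 0.285 and 0.648. Cells with intact Prmt1 would pull the library toward control cells, but the slope of the deviation on the knockout effect was at least 0.0736 and so pointed away, and Prmt1 was lowest in library 1 in every fraction. Lower depth applies to 1 fraction of 3. What sets these libraries apart stays open.

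Prmt1 made up less of Heavy than of Light RNA in all knockout pairs, the reverse of control cells. A general loss of contrast between the pools would bring the difference toward 0 without crossing it, yet the highest knockout value was -0.69. Coding length does not account for it, as the interaction was -1.49 with the trend removed. Transcripts of the recombined allele might be read out early and carry fewer ribosomes, which gene-level values cannot test.

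Regrouping the 6 libraries or cultures of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, reached its count in Total, Light, Heavy, Heavy over Light, Heavy over Total and control Heavy against Light. The highest other split called 0 genes, or 3 in control Heavy against Light.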

How the results depend on the processing

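The alternatives with voom, median-of-ratios scaling, coding length or all knockout libraries numbered 1 were chosen after the results were seen, and the cause of the changes they bring was not tested. With a deposited value of at least 5 (31 CPM) in 3 libraries the count was 1808 in Total, 3657 in Light, 2653 in Heavy, 5361 in control Heavy against Light, 0 in Heavy over Total and 655 in Heavy over Light, 637 of them toward Light. Leaving out 1 library gave 3598 to 4049 in Total, 5642 to 6534 in Light, 3951 to 5593 in Heavy, 7 to 2011 in Heavy over Light, 1 to 9 in Heavy over Total and 8004 to 8628 in control Heavy against Light. Prmt1 was then -0.77 to -0.64 in Total (limma adjusted p = 0.0364 to 0.0809), -0.29 to -0.04 in Light and -2.11 to -1.53 in Heavy. Heavy called 2976 genes with its own libraries alone. Heavy over Light called 152 genes after quantile normalization, 756 without trend, 8 with its own libraries alone, 335 with voom, 49 after median-of-ratios scaling, 23 with the coding-length trend removed and 1872 without the knockout libraries numbered 1. Heavy over Total called 1 without a filter, 0 with a pseudocount of 0.1, 0 with voom, 0 at a mean of at least 1 CPM, 1 among coding genes, 1 with the coding-length trend removed and 4 without the knockout libraries numbered 1. There Cngb1 lost its call in most alternatives, and 4833412C05Rik became -0.31 with voom (adjusted p = 0.990).

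With replicate numbers as a block, the count was 5828 in Total, 6339 in Light, 384 in Heavy, 10 in Heavy over Light, 1 in Heavy over Total and 10036 in control Heavy against Light. Prmt1 in Heavy was -1.88 under the block (blocked adjusted p = 0.0673). The block and removal of the coding-length trend together gave 925 in Heavy over Light and 0 in Heavy over Total. In no comparison of knockout with control did every library deviate most like that of its own number. Heavy knockout 3 correlated more with Light knockout 2 (0.545) than 3 (0.263). Correlations of the same number between knockout and control libraries were -0.208 to 0.602 in Total, -0.075 to 0.104 in Light and -0.487 to -0.276 in Heavy, and between Heavy and Total -0.506 to 0.157 in control and 0.03 to 0.535 in knockout cells. With the block 0 genes were called higher in Light and lower in Heavy. Lists passing with the block were 19 in Total, 9 in Light, 19 in Heavy, 11 in Heavy over Light, 6 in Heavy over Total and 18 in control Heavy against Light.

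With the coding-length trend removed, some directions reversed. Genes in Light were Vwf (-0.13), Atad3a (-0.0245), Fbxo42 (-0.00393), Racgap1 (-0.0344) and Nsun2 (-0.0624), and in Heavy Vwf (-0.15). In control Heavy against Light, with the block and without it, they were Cxcl1 (0.00705), Car2 (0.25), Matn3 (-0.00517), Cldn7 (0.61) and Eif4e (0.32). The median turned to -0.0912 for histones in Heavy over Light, and to 0.23 for ribosomal proteins and 0.26 for histones in control Heavy against Light. For oxidative phosphorylation the median kept its sign, at -0.0452 in Light and -0.0769 in control Heavy against Light, and only camera's direction, no longer called, turned to up. Oxidative phosphorylation in Heavy over Total ranged from -0.358 to 0.0672 when 1 library was left out, reversed without Heavy knockout 1, and was 0.10 without all knockout libraries numbered 1. The planned count fits (size factors, library size alone, Wald test) were not run, although the recovered reads would allow them.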

Other observations

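The check of these observations was chosen after they were seen. A set of 40 genes was called higher in Light and lower in Heavy RNA of knockout cells, and 0 genes the other way. The set includes the translation elongation subunit Eef1g (Light 0.39, Heavy -0.52), the nuclear pore protein Nup85 (0.41 and -0.52), the chromatin remodelling subunit Actl6a, which overlaps Mrpl47 (0.40 and -0.53), and the histidine tRNA ligase Hars, which overlaps Hars2 (0.38 and -0.34). In Total 9 of the set were called, all lower. Weaker loading of these messages with ribosomes is 1 reading, but the set might reflect processing: 16 genes met the same criterion after median-of-ratios scaling (1 of the 40, and 5 genes the other way), 18 after quantile normalization (16 of the 40, and 5 the other way) and 10 with the coding-length trend removed (4 of the 40, and 7 the other way). With the libraries of each comparison alone 4 genes met it, and without all knockout libraries numbered 1 it was 99, with 20 the other way. Most of the set met it with voom (32 of the 40), without a filter (38), with a pseudocount of 0.1 (35), with a deposited value of at least 5 in 3 libraries (39), at a mean of at least 1 CPM (40) and without trend (40). Spike-in RNA in each fraction, or quantitative PCR for Eef1g and Nup85 across all gradient fractions, would tell.

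Interferon-stimulated genes had medians of 0.80 in Total and 0.95 in Heavy RNA (adjusted p = 0.316 and 0.493 with an estimated correlation) and of 0.06 in Heavy over Total (camera adjusted p = 0.868). Without all knockout libraries numbered 1 these medians were 0.62, 0.77 and 0.03 (Heavy over Total adjusted p = 0.734). The response could therefore lie in message abundance more than in loading, but Heavy over Total was -0.15 (adjusted p = 0.00401) without Heavy knockout 1 alone and 0.21 (0.00902) without Total knockout 1 alone. Blocking JAK kinases in knockout cells, and 4-hydroxytamoxifen in cells without floxed alleles, would test whether interferon signalling or the drug is the source. Cdkn1a and Bcl2l11 rose in all fractions although the cells derive from p53-deficient mice, so a p53-independent arrest may be looked for by DNA content and by Cdkn1a protein, while the median of DNA replication genes in Total without the libraries numbered 1 was -0.20.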
